A study of Caenorhabditis elegans with 16 samples.

How the data were processed

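Small RNA from whole adult male C. elegans was sequenced in 16 libraries of 4 genotypes. The genotypes were wild type (5 libraries), a prg-1 null mutant (5), a prg-1 RNase mutant (3) and a prg-1 mutant without the PAZ domain (ΔPAZ, 3). prg-1 encodes the Piwi-clade Argonaute protein that binds piRNAs, the 21U-RNAs of this worm. Per the labels' protocols, between 20 and 30 males per sample were picked at mid-L4, grown at 25 °C and collected 24 hours later. The extracted small RNA was treated with a pyrophosphatase before library preparation, so small RNAs with a 5′ triphosphate could enter the libraries as well. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

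Reads were trimmed with cutadapt 3.7 and inspected with FastQC 0.12.0, per the submitters' processing notes. The aligner, the mismatches allowed and the handling of reads that map to several places are not given in the sources used here. Per the file headers, the authors deposited read counts per library (total, mapped to the genome, all piRNA and 21U-only piRNA), sense and antisense counts for each of 15913 piRNA names of piRNAdb, and counts per 100 kb bin of the ce11 genome. Per the file headers, the authors also give all piRNA and 21U-only reads as RPM, reads per 1000000 genome-mapped reads. The rule by which a read was counted as 21U only is not given in the sources used here. All RPM values below were recomputed from the counts with genome-mapped reads as the denominator, and matched the authors' deposited RPM. Sense reads at piRNA loci that were not counted as 21U only are called other sense reads.

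The per-piRNA table was checked before use. Column totals equalled the piRNA totals of each library, after 1 cell that was not a number was set to 0. The 3 ΔPAZ columns began with their own total and were moved up by 1 row. The columns do not share a row order. Rows with a read in both of 2 libraries were 17.0 times as frequent as by chance between wild type replicates 1 to 3 and null replicates 1 to 3. The same ratio was 0.888 between wild type replicates 1 to 3 and the RNase columns, and 0.930 between wild type replicates 1 to 3 and the ΔPAZ columns. In null replicate 4, 66.5% of detected piRNAs fell among the alphabetically first names, against 3.14% by chance. Tests of single piRNAs were therefore made only between null replicates 1 to 3 and wild type replicates 1 to 3. Whether the names beside these columns belong to their rows could not be tested. Sums, the number of piRNAs detected and the concentration of reads do not depend on row order and used all 16 libraries. The planned piRNA by piRNA tests of the other 5 pairs of genotypes were replaced by tests on the 1006 genome bins, a choice made after the files were seen. Bins were annotated with Ensembl release 115 of WBcel235, the same assembly as ce11, and let-7 was placed with the RefSeq table of that assembly. A bin holds many genes, and its reads cannot be assigned to one of them or to a strand.

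Depth ranged from 396813 to 2288967 genome-mapped reads and from 258 to 8515 piRNA reads per library, so 1 read was worth most in ΔPAZ replicates 1 and 2. Per-library shares carry Wilson 95% intervals, and a piRNA without reads is given an upper limit of 3 counts over the group. These intervals and limits, and the 95% intervals of ratios of counts, cover counting error only, since reads of amplified libraries are not independent molecules. Libraries of the same genotype were compared over the bins, and no pair came near sampling noise: chi-square per degree of freedom was at least 41.2.

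Single measures were compared between genotypes by exact two-sided permutation tests of the difference in means, with Benjamini-Hochberg adjustment over the 6 pairs of genotypes (over the 3 mutants for concentration). With 5 against 5 libraries the smallest possible p is 0.00794, with 5 against 3 it is 0.0357 and with 3 against 3 it is 0.1, so with 5 against 3 libraries an adjusted p under 0.05 over 6 pairs needs the smallest p in every pair except RNase against ΔPAZ. 21U-only reads, other sense reads, the 21U-only percentage and antisense reads were tested as measures added after the files were seen. The number of piRNAs detected is the expected number with at least 1 read after thinning to the lowest genome-mapped total, and as an alternative to the lowest number of piRNA reads. Concentration is the percentage of piRNA reads in the 100 rows with most reads.

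Counts per piRNA and per bin were tested with edgeR 4.0.16 (quasi-likelihood F test, all groups in one fit for bins) in R 4.3.3, with genome-mapped reads as library size, no further factors, a count of at least 10 in at least 3 libraries, and Benjamini-Hochberg adjusted p under 0.05. The standard error of a fold change was taken from the fold change and its F statistic. Groups of bins were tested with camera (limma 3.58.1, preset correlation 0.01 and an estimated one) and fry. They were chromosome IV, chromosome X, the other chromosomes, the piRNA clusters of chromosome IV (cluster 1, 4500001 to 7000000, and cluster 2, 13500001 to 17200000), bins with microRNA, tRNA or rRNA genes, and 4 classes of mean abundance. The planned grouping by first base and length was not run, since single piRNAs had no sequence or position here. The overlap of calls between mutants was compared with 50 simulations of unchanged groups, with independent lists and with 10 splits of the wild type libraries. Named piRNAs and bins followed one rule: the 10 highest in wild type, and for each mutant up to 5 largest rises and 5 largest falls with a mean count of at least 50 in the higher group and every mutant library on the same side of the wild type mean. Bins with let-7, lin-4, mir-1, mir-35, mir-71, mir-124 and lsy-6 were added as markers of other cell types or as controls. The tests, the naming rule, these lists and the alternatives for total piRNA reads, piRNAs detected, concentration and single piRNAs were set before the data were examined, and their use on bins, with 2 lists of microRNAs joined into 1 list of 7, was chosen later.

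The fits were tested on simulated counts. With 200 of the 1006 bins changed, the null against wild type fit recovered 76.9% of 2-fold and 100% of 4-fold changes, with 8 false calls. For RNase against wild type it recovered 63.6% of 2-fold and 98.2% of 4-fold changes, and for ΔPAZ against wild type 58.4% and 98.0%. Counts were simulated independently for each bin, without shifts common to many bins. The false calls are therefore not an error rate for the real libraries. Alternatives covered the 13 libraries of the series' design text, replicates 1 to 3 alone, other scalings (TMM, library size without the 3 largest bins, size factors), DESeq2 1.42.0, count filters, a replicate block, a block of replicates 1 to 3 against replicates 4 and 5 (called the block below), fits of 2 groups, and leaving out each library. Python 3.11.15, numpy, pandas and scipy were used for the remaining steps.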

Results

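Small RNA libraries from whole adult males addressed how piRNA levels differ between wild type C. elegans and prg-1 mutants. The 16 libraries came from wild type (n = 5), prg-1 null (n = 5), prg-1 RNase mutant (n = 3) and prg-1 ΔPAZ (n = 3) males. PRG-1 is the Piwi Argonaute that binds 21U-RNAs, its PAZ domain is the part of an Argonaute that holds the 3′ end of a small RNA, and the RNase mutant is called RNase dead in the series' design text. The design text lists 13 of the libraries; wild type replicates 4 and 5 and null replicate 5 are the others. Genome-mapped reads per library numbered 1192841 ± 410185 (SD, n = 5) in wild type, 1785976 ± 397213 (n = 5) in the null, 1584509 ± 597619 (n = 3) in the RNase mutant and 671674 ± 279039 (n = 3) in ΔPAZ. The share of reads that mapped to the genome was 53.2 ± 12.4% in wild type. It was 73.0 ± 8.47% in the null (exact permutation p = 0.0397, two-sided, as all p-values of single measures here) and 72.8 ± 4.13% in the RNase mutant (exact permutation p = 0.0357). In ΔPAZ it was 47.0 ± 4.92% (exact permutation p = 0.536).

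Males without PRG-1 had almost no 21U-only reads. These made up 1266 ± 631 RPM in wild type (SD, n = 5) and 12.1 ± 5.77 RPM in the null (n = 5), 105 times less. Other sense reads at piRNA loci fell from 774 ± 149 to 364 ± 152 RPM, 0.471 of wild type, and antisense reads at the same loci were at 111 ± 32.6 RPM in wild type and 114 ± 21.6 RPM in the null. Of the sense reads left at piRNA loci in the null, 3.91 ± 2.57% were 21U only, against 59.5 ± 9.81% in wild type. All sense piRNA reads together fell from 2039 ± 774 to 377 ± 148 RPM.

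Every null library lay below every wild type library in all of these sense measures, and the exact permutation test gave p = 0.00794 for each, the smallest that 5 against 5 libraries allow (adjusted p = 0.0476 over 6 pairs of genotypes). With libraries permuted only within replicates 1 to 3 and within replicates 4 and 5 the exact permutation p was 0.0167 for each, the smallest possible (adjusted p = 0.1). For antisense reads the exact permutation p was 0.802, and the ratio to wild type was 0.937 to 1.12 with 1 library left out. The authors' deposited table gives 0.957% of wild type for 21U-only reads in the null, the ratio of the means here being 0.00957. The null libraries held 17, 27, 39, 5 and 20 such reads, and in null replicate 4 the share of 21U-only reads was 0.576% (Wilson 95% interval 0.246 to 1.34%). Within replicates 1 to 3 the null had 0.118 of wild type piRNA reads (exact permutation p = 0.1, the smallest possible), and within replicates 4 and 5 it had 0.327 (n = 2 each). Other sense reads in the null were 0.320 of wild type in replicates 1 to 3 and 0.727 in replicates 4 and 5, and 0.650 over all replicates with total reads as the denominator (exact permutation p = 0.159).

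Most of the single piRNAs tested fell as well. cel-piR-6101, the most abundant in wild type, went from 169 ± 57.4 RPM (747 reads in 3 libraries) to 2 reads in 3 null libraries, a ratio of counts of 468 (95% interval 129 to 3867). cel-piR-733 went from 84.8 ± 42.6 RPM (n = 3) to 1 read, and cel-piR-4338 from 60.8 ± 17.95 RPM to 1 read. No read of cel-piR-871, cel-piR-8248 or cel-piR-15599 was found in the null, where they were at least 92.8, 89.5 and 67.9-fold lower (against 3 counts over the group, 0.577 RPM). cel-piR-6735 and cel-piR-3162 also fell, to 2 reads and 1 read. Among the most abundant, cel-piR-156 and cel-piR-1592 were not called: cel-piR-156 was at 34.3 ± 5.50 RPM in wild type and 47.1 ± 7.34 RPM in the null (log2 fold change 0.45, adjusted p = 0.450), and cel-piR-1592 at 32.9 ± 29.3 and 16.5 ± 5.14 RPM (adjusted p = 0.298).

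Of 27 piRNAs tested between null replicates 1 to 3 and wild type replicates 1 to 3, 19 were lower and 0 higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 8 were not called; DESeq2 gave the same counts. All null libraries lay below all wild type libraries for 19 piRNAs and above them for 2, each against 5% expected by chance (10% for both directions). The median log2 fold change was -6.78, or -4.94 with the 10 piRNAs without null reads set to their bound. These 27 held 35.8% of wild type and 50.6% of null piRNA reads. Against total piRNA reads in place of genome-mapped reads, the 8 were called higher and the 19 lower. The names follow the deposited order of rows, which could not be checked for these columns. By 4 classes of abundance, 4 of 7, 6 of 7, 4 of 6 and 5 of 7 piRNAs fell, with fry p between 0.00124 and 0.00516 and no call by camera, which compares a class with the others.

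**Figure D1:**
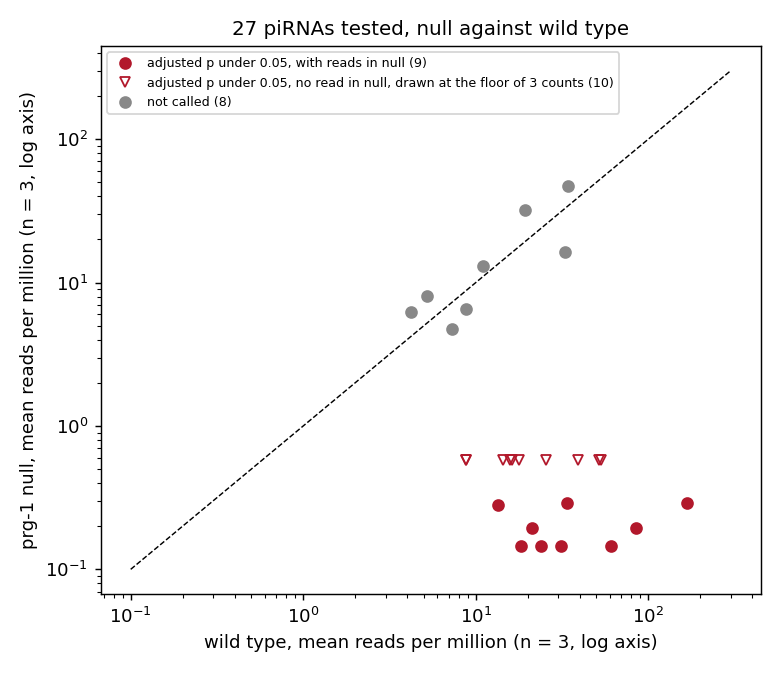
Mean RPM of each of 27 piRNAs in wild type (horizontal, log axis, n = 3) and in the null (vertical, log axis, n = 3), with the line of equal levels. The 19 called piRNAs lie far below the line, 10 of them without a null read and drawn at the floor of 0.577 RPM, and 8 lie near it.

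Fewer piRNAs were detected in the null, which also had fewer piRNA reads to detect them with. At equal genome-mapped depth 71.9 ± 33.0 piRNAs (SD, n = 5) were detected, against 298 ± 121 in wild type (exact permutation p = 0.00794, adjusted p = 0.0476). At equal numbers of piRNA reads (258 per library) the numbers were 97.6 ± 22.2 and 142 ± 20.6 (exact permutation p = 0.0238), and the adjusted p of 0.0714 missed the threshold. The 10 piRNAs with most reads in each library took 47.9 ± 9.24% of the null's reads and 27.0 ± 1.58% of wild type reads (exact permutation p = 0.00794). The first 100 took 90.2 ± 10.3% and 70.0 ± 12.4% (exact permutation p = 0.0317, adjusted p = 0.0536), a measure that reaches 100% in null replicate 1, which has 87 piRNAs. Within replicates 1 to 3 the null had 0.141 of the wild type number detected and 1.52 times the percentage in the first 100 (exact permutation p = 0.1 for each, the smallest possible), and within replicates 4 and 5 it had 0.478 and 1.00 (n = 2 each). The number at equal piRNA reads was 0.544 of wild type in replicates 1 to 3 and 0.952 in replicates 4 and 5. At equal piRNA reads the first 100 took 96.8 ± 4.96% in the null and 83.9 ± 7.90% in wild type (exact permutation p = 0.0238). This difference missed the adjusted threshold. Null replicates 1 to 3 hold only 78.7 to 89.8 piRNAs at that number of reads, so their value is 100% by construction.

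Across the genome small RNA of the null differed from wild type in many 100 kb bins, and the larger piRNA cluster of chromosome IV was among the regions that lost reads. In that cluster (cluster 2, IV 13500001 to 17200000, ce11; 37 bins with 11388 annotated piRNA genes) 23 bins fell and 3 rose, and the median log2 fold change was -1.002, against -0.15 elsewhere on chromosome IV. The smaller cluster (cluster 1, IV 4500001 to 7000000, 25 bins with 2816 piRNA genes) had 5 bins lower and 4 higher and a median of -0.17. The strongest rises lay outside both clusters: chromosome V 200001 to 300000, with 18 protein-coding genes, went from 105 ± 11.6 to 2951 ± 521 RPM (log2 fold change 4.81, SE 0.26, adjusted p = 6.5e-12). Chromosome IV 3300001 to 3400000 rose from 105 ± 58.8 to 2891 ± 676 RPM (4.79, SE 0.34), and chromosome I 14800001 to 14900000 from 460 ± 167 to 6315 ± 939 RPM (3.78, SE 0.29).

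Further bins with large rises were chromosome III 10300001 to 10400000 (log2 fold change 3.46) and chromosome IV 2700001 to 2800000 (2.98). The largest falls were on chromosomes X and V. Chromosome X 200001 to 300000, which holds mir-258.2, fell from 491 ± 161 to 14.9 ± 5.65 RPM (log2 fold change -5.04, SE 0.33, adjusted p = 2.1e-10). The others were X 16700001 to 16800000 (-4.00), X 4100001 to 4200000 (-3.94), X 100001 to 200000 (-3.67) and V 17700001 to 17800000 (-3.59). Among the 7 bins with marker microRNAs 0 were called in the null by edgeR, adjusted over the list alone or over all bins, 0 had an unadjusted p under 0.05 and DESeq2 called 0. Their log2 fold changes ran from -0.39 (mir-35, of germline and embryo) to 0.34 (mir-124 of neurons and lin-4 of developmental timing). With TMM factors the mir-124 bin was called higher (0.69, adjusted p = 0.000853).

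In all, 405 of 1006 bins were called, 121 higher and 284 lower, and the median over all bins was -0.29. With TMM factors the median moved to 0.02 and the calls to 238 higher and 191 lower, so whether most changed bins rose or fell depends on the scaling. With replicates 1 to 3 and replicates 4 and 5 as a block 441 bins were called (136 higher, 305 lower), 402 of them among the 405. Of the 405, 402 had the same direction of fold within replicates 1 to 3 and within replicates 4 and 5. The 405 were chosen with these same libraries, so this agreement is not a replication. Replicates 4 and 5 fitted alone called 350 bins, 292 of them shared with the 405, and these libraries had also entered the main fit. Cluster 2 on chromosome IV was low with both scalings (TMM median -0.73, camera adjusted p = 4.2e-05 with a preset correlation of 0.01, 8.1e-05 with TMM, fry adjusted p = 0.000716), but not with an estimated correlation (adjusted p = 0.980). By the same test the 252 bins with fewest reads were lower (median -0.48, adjusted p = 0.0101) and the 252 with most reads higher (median 0.17, adjusted p = 6.0e-07), both with adjusted p = 0.980 with an estimated correlation. Chromosome X, chromosome IV as a whole, the other chromosomes and the bins with microRNA, tRNA or rRNA genes were not called by camera (lowest adjusted p = 0.0672, for chromosome X, which was lower with TMM factors at adjusted p = 0.0255). By fry chromosome X (adjusted p = 0.000747) and the bins with tRNA genes (adjusted p = 0.0411) were lower as well. fry does not compare a group with the other bins, so its calls may reflect the median of -0.29 over all bins. It does not set cluster 2 apart.

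**Figure D2:**
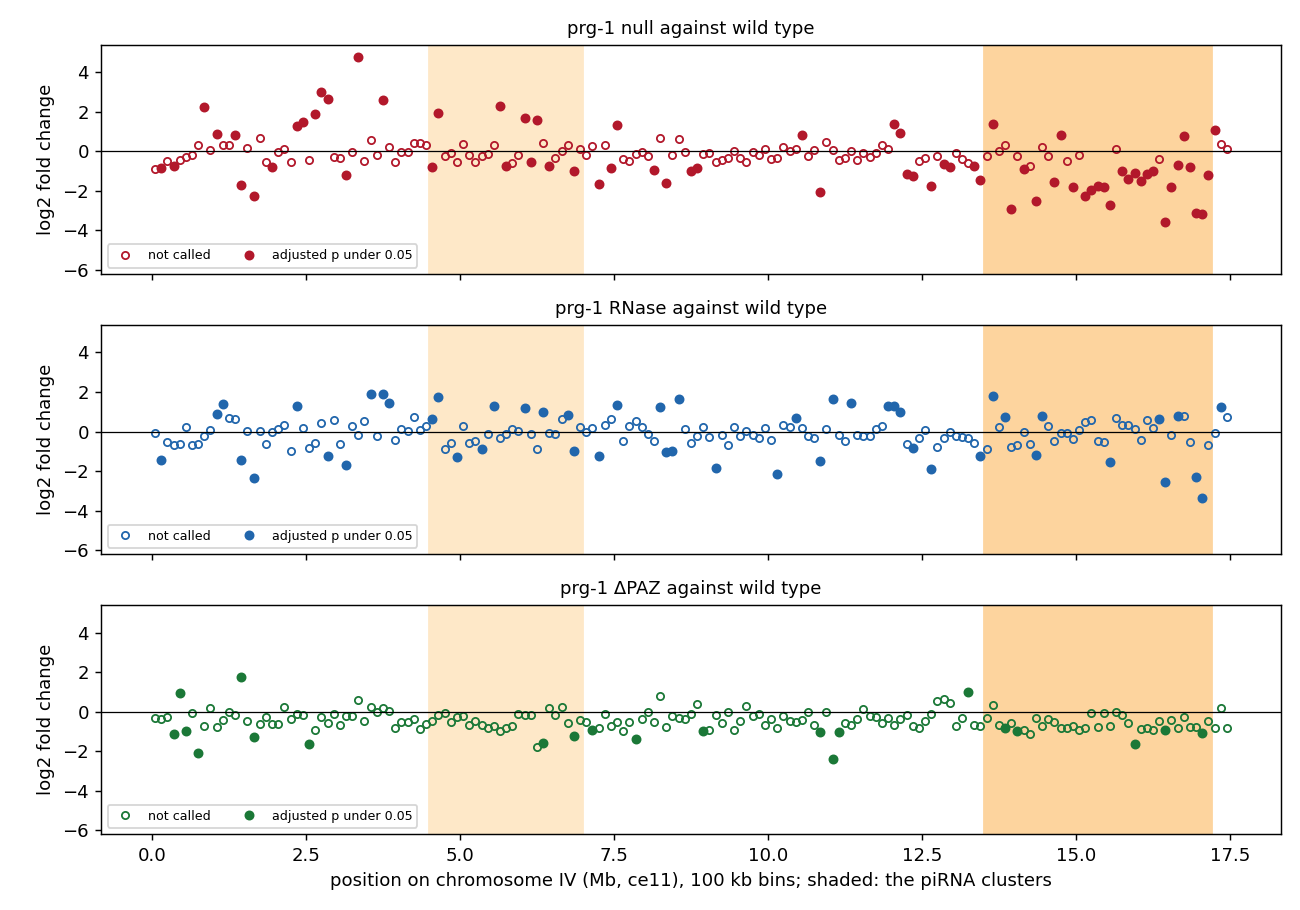
Log2 fold change of each 100 kb bin of chromosome IV (vertical) by position in Mb (horizontal, ce11) for each mutant against wild type, filled where edgeR's adjusted p is under 0.05. The shaded spans are piRNA clusters 1 (left) and 2 (right). In the null 23 of the 37 bins of cluster 2 are lower, and in the RNase mutant its median is -0.05.

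Males with the RNase mutant protein had 21U-only reads within the range of the wild type libraries, and in each library more of the other sense reads at piRNA loci. 21U-only reads were at 1089 ± 307 RPM (SD, n = 3), 0.860 of wild type. This ratio was 0.720 within replicates 1 to 3, 1.12 with total reads as the denominator and 1.06 without wild type replicate 2. Other sense reads were at 2066 ± 566 RPM, 2.67 times wild type, and each RNase library (1427 to 2506 RPM) lay above each wild type library (627 to 997 RPM). The share of 21U-only reads was 34.5 ± 1.24%, below every wild type library (lowest 42.9%). In all, piRNA reads were at 3155 ± 869 RPM, 1.55 times wild type, and antisense reads at 189 ± 46.9 RPM. The 3 bins with most reads took 11.9 ± 2.11% of RNase reads and 24.5 ± 8.65% of wild type reads (exact permutation p = 0.0357). The piRNA totals were not recomputed without those bins, so the size of the RPM ratios may depend on the scaling.

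For other sense reads and for the 21U-only share the exact permutation p was 0.0357, the smallest that 5 against 3 libraries allow, and the adjusted p of 0.0536 missed the threshold. The exact permutation p was 0.714 for 21U-only reads, 0.107 for all piRNA reads (adjusted p = 0.107) and 0.107 for antisense reads. The authors' deposited table gives 86.0% of wild type for 21U-only reads. At equal depth 536 ± 140 piRNAs were detected (exact permutation p = 0.0714), at equal numbers of piRNA reads 183 ± 9.14 (exact permutation p = 0.0357, adjusted p = 0.0714), and the first 100 took 48.4 ± 4.65% of reads (exact permutation p = 0.0357, adjusted p = 0.0536). With the first 10, at 17.5 ± 2.47%, the adjusted p was 0.0357 by the same exact test. At equal numbers of piRNA reads the first 100 took 67.3 ± 4.01%, against 83.9 ± 7.90% in wild type (exact permutation p = 0.0357). This difference missed the adjusted threshold. Bins with rRNA genes held 5.80 ± 1.69% of reads, against 13.7 ± 7.19% in wild type (exact permutation p = 0.0714).

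Small RNA from single regions rose by a wide margin in the RNase mutant. Chromosome V 9800001 to 9900000 went from 70.9 ± 16.5 RPM (n = 5) to 2051 ± 161 RPM (n = 3), with a log2 fold change of 4.86 (SE 0.43, adjusted p = 3.8e-08). Chromosome III 2500001 to 2600000 rose from 96.1 ± 19.3 to 1556 ± 132 RPM (4.02, SE 0.27), and X 1100001 to 1200000 (3.96) and X 1500001 to 1600000 (3.31) rose as well. Chromosome V 17600001 to 17700000 rose from 312 ± 78.6 to 2794 ± 105 RPM (3.16, adjusted p = 3.0e-08); in the null the same bin fell to 115 ± 18.7 RPM (-1.45, adjusted p = 5.7e-05). The bin of let-7, a microRNA of developmental timing, rose from 660 ± 171 to 3485 ± 445 RPM (log2 fold change 2.40, SE 0.34, adjusted p = 1.4e-05).

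Chromosome X 200001 to 300000 was nearly lost here too, at 8.20 ± 3.33 RPM (log2 fold change -5.95, SE 0.45). Chromosome I 2900001 to 3000000, one of the bins with most reads in wild type (40195 ± 29329 RPM), fell to 1068 ± 74.5 RPM (-5.23, SE 0.99, adjusted p = 0.000332), and it was lower in the null as well (-2.23, adjusted p = 0.0132). X 16700001 to 16800000 (-4.12), I 10800001 to 10900000 with mir-1817 (-3.64, or -2.92 with the block) and V 20400001 to 20500000 (-3.58) also fell. Among the bins with most reads in wild type, III 8800001 to 8900000 with mir-80, mir-90 and mir-238 rose from 35400 ± 16162 to 101225 ± 11736 RPM (1.52, adjusted p = 0.0202; 1.42 and adjusted p = 0.0728 without RNase replicate 2). IV 5500001 to 5600000, with mir-228 and 211 piRNA genes, had a log2 fold change of 1.31 (adjusted p = 0.0349), and its call held in 2 of 8 fits that left out 1 library (adjusted p up to 0.0905) and ended with the block (1.04, adjusted p = 0.0543).

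Of the other bins with most reads, none was called in any mutant: IV 12700001 to 12800000 with 4 snRNA genes, I 15000001 to 15100000 with 4 rRNA genes, V 17100001 to 17200000 with 14 rRNA genes, II 7800001 to 7900000 with mir-57, IV 9300001 to 9400000, X 2400001 to 2500000 with mir-81 and mir-82, and IV 4700001 to 4800000. With TMM factors the mir-81 and mir-82 bin was called in the null (adjusted p = 0.0138; 0.0456 with the block). With the block IV 12700001 to 12800000 (-1.42), IV 9300001 to 9400000 (-1.41) and IV 4700001 to 4800000 (-1.60) were called lower in the RNase mutant, and V 17100001 to 17200000 (2.55) higher in ΔPAZ. In the RNase mutant V 17100001 to 17200000 had a log2 fold change of -2.30 (adjusted p = 0.0543), was called in 3 of 8 fits that left out 1 library and was at -0.35 with the block. Of the 7 marker bins 2 rose in the RNase mutant, adjusted over the list alone and over all bins: let-7 and mir-71, the latter with a log2 fold change of 1.10 (SE 0.35, adjusted p = 0.0182 over the list alone, 0.0218 over all bins). The mir-71 call ended without any one of the RNase replicates (adjusted p 0.0521 to 0.0651). The bins of lin-4 (0.57), lsy-6 of neurons (0.04), mir-1 of muscle (-0.54), mir-124 (0.29) and mir-35 (0.44) were not called, except mir-124 with TMM (0.44, adjusted p = 0.0454).

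A total of 312 bins were called in the RNase mutant, 145 higher and 167 lower (edgeR quasi-likelihood test), with a median of -0.12. TMM factors gave a median near 0 and 212 higher against 167 lower, the block 179 and 161, and library sizes without the 3 bins with most reads 119 and 275. Chromosome IV cluster 2, with 5 bins higher and 5 lower, had a median of -0.05 (camera adjusted p = 0.529), and cluster 1 a median of -0.11 (adjusted p = 0.626). The 252 bins with most reads were higher as a group (median 0.21, adjusted p = 0.00202), but not with an estimated correlation (adjusted p = 0.980). No other group was called by camera, and fry called only the bins with rRNA genes, as lower (adjusted p = 0.0411).

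ΔPAZ males had fewer reads of each kind at piRNA loci on average, in proportions near those of wild type. 21U-only reads were at 617 ± 384 RPM (SD, n = 3), 0.487 of wild type (0.312 without ΔPAZ replicate 3), and other sense reads at 364 ± 157 RPM, 0.471 of wild type. The 21U-only share was 61.4 ± 6.51%, against 59.5 ± 9.81% in wild type, a ratio that was 0.958 within replicates 1 to 3 and 0.964 to 1.09 with 1 library left out. All piRNA reads were at 981 ± 536 RPM, 0.481 of wild type, and ΔPAZ replicate 3 (1599 RPM) lay among the wild type libraries. RPM are shares of genome-mapped reads, and the 3 bins with most reads took more of these in ΔPAZ (37.8 ± 6.99%, against 24.5 ± 8.65%). The piRNA totals were not recomputed without those bins, so the size of these ratios may depend on the scaling.

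None of these differences passed the adjusted threshold. The exact permutation p was 0.0357 for other sense reads (adjusted p = 0.0536), 0.0714 for all piRNA reads (adjusted p = 0.107), 0.143 for 21U-only reads (adjusted p = 0.214), 0.893 for the 21U-only share and 0.143 for antisense reads, at 73.2 ± 35.4 RPM. The authors' deposited table gives 48.7% of wild type for 21U-only reads. At equal depth 118 ± 70.0 piRNAs were detected, 0.396 of wild type (exact permutation p = 0.0714; 0.262 of wild type without ΔPAZ replicate 3), at equal numbers of piRNA reads 94.1 ± 30.1 (exact permutation p = 0.0714), and the first 10 took 35.9 ± 7.09% of reads (exact permutation p = 0.0357, adjusted p = 0.0357). The first 100 took 91.9 ± 14.1% (exact permutation p = 0.0714), including ΔPAZ replicates with 70 and 97 piRNAs, where it is 100% by construction. The first 10 were counted at unequal numbers of piRNA reads. At equal numbers the first 100 took 96.5 ± 6.01%, against 83.9 ± 7.90% in wild type (exact permutation p = 0.0714). ΔPAZ replicates 1 and 2, with 70.0 and 84.3 piRNAs at that number of reads, are again at 100% by construction.

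Small RNA along the genome was called changed in fewer bins in ΔPAZ, and most of these calls were lost when certain libraries were left out. Chromosome V 17600001 to 17700000, which rose in the RNase mutant and fell in the null, was at 656 ± 272 RPM in ΔPAZ (log2 fold change 1.07, SE 0.27). IV 11000001 to 11100000, with mir-51 and mir-53, was at 292 ± 55.4 RPM in ΔPAZ and 1546 ± 995 RPM in wild type (-2.40, SE 0.54), while the RNase mutant had 4833 ± 1056 RPM (1.64, adjusted p = 0.0105; 0.0539 without RNase replicate 3). The other bins with large log2 fold changes were I 12300001 to 12400000 (2.51), X 2100001 to 2200000 (2.24), IV 13200001 to 13300000 (1.01), X 12500001 to 12600000 (0.99), V 13300001 to 13400000 (-2.35), IV 700001 to 800000 (-2.09), X 9300001 to 9400000 (-1.91) and I 8800001 to 8900000 (-1.74). Each of these 10 calls ended without ΔPAZ replicate 1 or without ΔPAZ replicate 2, while every fold kept its direction in all 8 fits that left out 1 library. For 8 of the 10 leaving out a ΔPAZ replicate moved the fold by less than 1.5 times: IV 11000001 to 11100000 stayed between -2.57 and -2.32, V 13300001 to 13400000 between -2.63 and -2.20, IV 700001 to 800000 between -2.22 and -1.96 and X 12500001 to 12600000 between 0.88 and 1.08. The others were I 12300001 to 12400000, at 1.35 without ΔPAZ replicate 1 (adjusted p = 0.0670), and X 2100001 to 2200000, at 0.20 without ΔPAZ replicate 2 (adjusted p = 0.786). IV 700001 to 800000 was at -1.44 without wild type replicate 3 and I 8800001 to 8900000 at -0.86 without wild type replicate 1. With the block 9 of the 10 were called, all but X 12500001 to 12600000 (0.82, adjusted p = 0.0680). With TMM factors the 5 rises were called and the 5 falls were not (-1.33 to -2.13, adjusted p 0.0553 to 0.161).

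In ΔPAZ 104 bins were called, 10 higher and 94 lower (edgeR quasi-likelihood test), with a median of -0.43. TMM factors gave a median of -0.03 and 44 calls, 28 higher and 16 lower, and the block 92 calls, 16 higher and 76 lower. The number was 4 without ΔPAZ replicate 1, 5 without ΔPAZ replicate 2, 199 without ΔPAZ replicate 3, 36, 364, 60 and 43 without wild type replicates 2, 3, 4 and 5, and 1 with the other genotypes left out of the fit. Relative to other bins, chromosome X was high (median -0.07 against -0.48; camera adjusted p = 1.0e-09; TMM median 0.32), with adjusted p = 0.242 with an estimated correlation. The other chromosomes (adjusted p = 0.00369; 0.114 with TMM, 0.382 with the block), the 252 bins with fewest reads (higher, adjusted p = 2.1e-07) and the third class of abundance (lower, adjusted p = 0.000183) were called with the preset correlation, and had adjusted p of 0.463 to 0.980 with an estimated one. With the block the bins with rRNA genes were called higher as well (median 0.36, adjusted p = 0.00875). Cluster 2 of chromosome IV had a median of -0.74, against -0.42 elsewhere on the chromosome (adjusted p = 0.116). Of the 7 marker bins 0 were called by edgeR, adjusted over the list alone or over all bins, and 0 by DESeq2. An unadjusted p under 0.05 was found for 2 of them, lin-4 (-0.94) and lsy-6 (-0.81; adjusted p = 0.0842 over the list alone for both). Bins with rRNA genes held 21.5 ± 10.5% of ΔPAZ reads (exact permutation p = 0.286 against wild type), and the 3 bins with most reads 37.8 ± 6.99%, against 24.5 ± 8.65% (exact permutation p = 0.107). For the rRNA bins each ΔPAZ library (14.3 to 33.5%) lay above wild type replicates 1 to 3 (6.71 to 12.3%), but not above all of replicates 4 and 5 (25.1 and 15.7%).

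Compared with each other, the RNase mutant and ΔPAZ each had many more 21U-only reads than the null in every library. The RNase mutant had 89.9 times and ΔPAZ 51.0 times the null's level (exact permutation p = 0.0357 for each, adjusted p = 0.0714), the latter 32.7 times without ΔPAZ replicate 3. All piRNA reads were 8.38 times and 2.61 times those of the null (exact permutation p = 0.0357, adjusted p = 0.0714), and the RNase mutant had 3.21 times as many as ΔPAZ (exact permutation p = 0.1, the smallest for 3 against 3). Without each library's 10 most abundant piRNAs the RNase mutant had 12.7 times the null's piRNA reads. With total reads as the denominator ΔPAZ had 1.68 times the null's piRNA reads (exact permutation p = 0.321), and the RNase mutant 4.84 times those of ΔPAZ. For other sense reads ΔPAZ and the null had a ratio of 1.00 (exact permutation p = 0.964), which was 0.642 with total reads as the denominator and 1.40 within replicates 1 to 3, and the RNase mutant had 5.67 times as many as either (exact permutation p = 0.0357 against the null, adjusted p = 0.0536), and 8.57 times ΔPAZ with total reads.

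The null and RNase mutants shared changes along the genome. Of their calls against wild type, 183 bins changed in the same direction in both, 54 higher and 129 lower, and 15 in opposite directions. With TMM factors 225 did so, 124 higher and 101 lower, so the balance of shared rises and falls depends on the scaling. Chromosome X 200001 to 300000, X 16700001 to 16800000 and V 17700001 to 17800000 fell in both, and V 200001 to 300000 and I 14800001 to 14900000 rose in both (RNase log2 fold changes 2.55 and 2.28). The first 3 of these falls were also called lower in ΔPAZ (log2 fold changes -1.08, -1.23 and -1.06, adjusted p 0.0332 to 0.0416), calls that ended with TMM factors (adjusted p 0.105 to 0.149) and held in 3, 4 and 3 of 8 fits that left out 1 library. With the block the ΔPAZ calls of X 200001 to 300000 (-0.98, edgeR adjusted p = 0.0636) and V 17700001 to 17800000 (-0.96, adjusted p = 0.0603) ended as well. That of X 16700001 to 16800000 (-1.25, adjusted p = 0.0318) held. Independent lists would share 64.6 bins, and splitting the wild type libraries between the comparisons gave 117 (109.5 to 132 over 10 splits). Simulated unchanged groups shared 0 bins in every pair of mutants. Unchanged groups give few calls to share, so this 0 is no test of the overlap. Fold changes of null and RNase had a correlation of 0.602, against 0.434 in the simulated groups. It was 0.146 against 0.43 for null and ΔPAZ, and 0.206 against 0.372 for RNase and ΔPAZ. The covariances, in the same order, were 0.637, 0.0834 and 0.12, against 0.0462, 0.0469 and 0.0473 in the simulated groups. The null and ΔPAZ shared 37 bins (27.7 if independent; 19.9 with split wild type libraries), and the RNase mutant and ΔPAZ 33 (17.05 and 16.7).

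Direct comparisons of the mutants called 213 bins for RNase against null (136 higher, 77 lower), 399 for ΔPAZ against null (176 higher, 223 lower) and 345 for RNase against ΔPAZ (250 higher, 95 lower). With TMM factors these were 257 (115 higher), 468 (216 higher) and 382 (211 higher). With library sizes without the 3 bins with most reads they were 218 (111 higher), 434 (281 higher) and 350 (138 higher), so the direction of most calls depends on the scaling in each of these comparisons. In principal components of the bins, PC1 (38.9% of variance) set wild type and ΔPAZ libraries apart from null and RNase libraries, and PC2 (18.4%) set RNase apart from null.

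**Figure D3:**
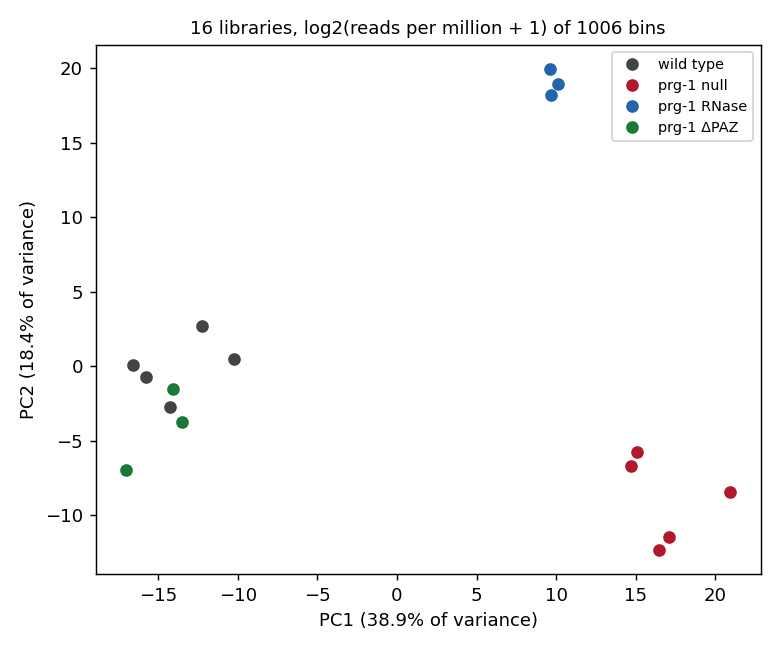
Principal components PC1 (horizontal, 38.9% of variance) and PC2 (vertical, 18.4%) of log2(RPM + 1) over 1006 bins, 1 point per library. The 5 null and 3 RNase libraries lie to the right of the 5 wild type and 3 ΔPAZ libraries.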

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

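The depth, RNA breakdown, abundant-piRNA and later-replicate tests of the RNase mutant, both tests of a few bins taking most reads, and the splits within sets of replicates, were chosen after the result was seen; the other tests in this part were not.

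Other sense reads at piRNA loci were 2.67 times as high in the RNase mutant as in wild type, in each of 3 libraries. Depth, RNA breakdown and a few abundant piRNAs were weighed. The ratio was 2.49 among libraries of similar depth (n = 2 and 3), which argues against depth, and 2.55 within replicates 1 to 3. Bins with rRNA genes took 0.422 of their wild type share. That share was highest in wild type replicates 4 and 5 (25.1 and 15.7%), and RNase replicate 2 (7.68%) lay above wild type replicate 2 (6.71%). It is also no direct measure of breakdown, so RNA breakdown stays open. All piRNA reads were at 1.76 of wild type without each library's 10 most abundant piRNAs. These include 21U-only reads, so whether a few piRNAs account for the other sense reads stays open too. A change in the processing or trimming of piRNAs in the RNase mutant may be a candidate explanation, as a hypothesis from these same data that was not tested. Read lengths were not analysed here. The adjusted exact permutation p of 0.0536 keeps the difference itself open.

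Most changed bins of ΔPAZ were lower than in wild type (94 of 104). With the 3 bins with most reads left out of the library sizes, 47.8% of 23 called bins were lower, so a few bins taking most of the reads may account for the direction. Depth does not: with every library thinned to the shallowest, 88.5% of called bins were still lower. Of 56 splits of the ΔPAZ and wild type libraries, 3 gave as many calls as the real one (104), so chance is not excluded. The highest other split, ΔPAZ replicates 1 and 2 with wild type replicate 3 against the rest, called 413. These 3 libraries also had the largest share of reads in the 3 bins with most reads (39.2, 44.1 and 35.1%), against at most 31.6% in the rest. The split keeps ΔPAZ replicates 1 and 2 together, so it does not separate genotype from other differences between libraries.

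The null and the RNase mutant changed 183 bins in the same direction. Sharing the wild type libraries is argued against, since with split wild type libraries the covariance of fold changes was 86.4% of that with shared ones. TMM factors gave 225 shared bins, 123% of the number, and library sizes without the 3 bins with most reads gave 247. A few bins taking most reads therefore does not account for the number of shared bins. With TMM more of them rose (124) than fell (101), and without the 3 bins 51 rose and 196 fell. The count does not show whether the same bins stay shared, so a part of such bins in which bins are shared, and in their direction, is not excluded. A change common to both prg-1 mutants is in line with these values, as a hypothesis. A difference between strains other than prg-1 itself was not tested and stays open. The null and RNase libraries also had a higher mapped share (73.0 ± 8.47% and 72.8 ± 4.13%) than wild type (53.2 ± 12.4%) and ΔPAZ (47.0 ± 4.92%). Whether such a difference between libraries accounts for the shared bins was not tested either.

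Other splits of the libraries argued against chance for the bins of null against wild type (405 calls, 1 of 100 splits, highest other 170). So did splits with libraries exchanged only within replicates 1 to 3 and within replicates 4 and 5 (1 of 60, highest other 144). Both take the libraries of a genotype as independent. The labels do not say that replicates came from separate cultures, so a difference between cultures is not excluded. RNase against wild type (312 calls) had 1 of 56 splits as large with both sets of replicates exchanged (highest other 159). So did RNase against null (213, highest other 23) and ΔPAZ against null (399, highest other 31). These sets stood apart over the bins (exact permutation p = 0.02, one-sided), and the RNase mutant and ΔPAZ have only replicates 1 to 3. Free exchange is therefore not warranted, and chance is not excluded for these comparisons. Within replicates 1 to 3 the 20 splits were too few for a share under 0.05 (highest other 95, 5 and 31), as for ΔPAZ against wild type (2 of 20 as large as the real 104; highest other 413). The splits were too few for a share under 0.05 for RNase against ΔPAZ (345; 1 of 10; highest other 0) and for the piRNAs of null against wild type (19; 1 of 10; highest other 0).

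A library lay far from the others of its group in 6 of 108 groups of 5 libraries tested, and chance gives about 1 in 20. The 3 bins with most reads took 25.7% of reads in null replicate 1 and 17.3 to 19.7% in the other null libraries. The first 100 piRNAs took 91.3% of piRNA reads in wild type replicate 4 and 60.5 to 69.0% in the others. IV 12700001 to 12800000 had 272972 RPM in wild type replicate 3 (57052 to 117329 in the others). V 13300001 to 13400000 had 199.9 RPM in null replicate 1 (51.1 to 74.8), V 9800001 to 9900000 had 199.5 RPM in null replicate 2 (35.3 to 54.2) and X 100001 to 200000 had 32.9 RPM in null replicate 1 (7.07 to 11.6).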

How the results depend on the processing

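The alternatives for bins and their overlaps and groups, 21U-only reads and share, other sense and antisense reads, and those with replicates 1 to 3 alone, with replicates 1 to 3 and 4 and 5 as a block, or without the 10 most abundant piRNAs, and piRNAs detected at equal piRNA reads, were chosen after the data were seen; the rest were planned. Of 722 alternatives for 50 results, 586 kept direction and side of the threshold or, for counts, the range, 101 no longer passed it or fell under the range, 14 newly passed or exceeded it and 21 reversed, all of them for ratios that did not pass the threshold in either setting. The planned piRNA by piRNA tests of 5 pairs, and the grouping by first base and length, were not run; the 13 libraries, only 2 groups and the minimum of 50 counts gave no value for single piRNAs. Leaving out the filter removed no bin. Depth limits ΔPAZ most, where the shallowest library held 258 piRNA reads.

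The null's loss of piRNA reads kept its direction with fewer libraries, but could not pass the threshold because fewer libraries raise the smallest p. Its size changed by over 1.5 times with replicates 1 to 3 for all piRNA reads and for piRNAs detected. With 13 libraries the ratio to wild type was 0.138 for all piRNA reads, 0.00822 for 21U-only reads, 0.381 for other reads, 0.0692 for the 21U-only share and 0.169 for piRNAs detected. With replicates 1 to 3 these were 0.118, 0.0104, 0.320, 0.0893 and 0.141. With replicate block (same-numbered libraries as pairs, exact p = 0.0625) they were 0.185 for all, 0.00957 for 21U-only and 0.471 for other reads and 0.0657 for the share. With libraries permuted within replicates 1 to 3 and within replicates 4 and 5 (exact p = 0.0167, adjusted p = 0.1) the ratios were again 0.185, 0.00957, 0.471 and 0.0657, and 0.241 for piRNAs detected. Leaving out 1 library gave 0.157 to 0.215, 0.00829 to 0.0118, 0.399 to 0.509, 0.0551 to 0.0798 and 0.199 to 0.276. Other reads were at 0.650 with total reads as denominator, and piRNAs detected at 0.315 without thinning (adjusted exact p = 0.107) and at 0.690 at equal piRNA reads (adjusted exact p = 0.0714); the cause was not tested.

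Direction turned for 21U-only reads of RNase against wild type (0.860) at 1.12 with total reads and 0.745 to 1.06 with 1 library left out. It turned for other reads of ΔPAZ against null (1.00) at 1.18 with 13 libraries, 1.40 with replicates 1 to 3 and with replicate block, 1.004 on the log2 scale and 0.760 to 1.18 with 1 library left out. For the 21U-only share of ΔPAZ against wild type it turned at 0.958 with 13 libraries, with replicates 1 to 3 and with replicate block (0.964 to 1.09 with 1 library left out). For antisense reads of null against wild type it turned with 1 library left out (0.937 to 1.12), and for piRNAs detected in ΔPAZ against null at 0.856 without thinning and 0.964 at equal piRNA reads. The cause was not tested.

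Concentration in the first 10 piRNAs, at unequal numbers of piRNA reads, gave ratios of 1.77 (null), 0.648 (RNase) and 1.33 (ΔPAZ), all past the threshold. At equal numbers of piRNA reads the first 100 gave 1.15, 0.803 and 1.15 (exact permutation p = 0.0238, 0.0357 and 0.0714), none past the adjusted threshold. That null ratio was 1.25 within replicates 1 to 3, where each null library is at 100% by construction, and 1.03 within replicates 4 and 5. Without thinning, the null ratio for the first 100 ran from 1.25 to 1.40 with 1 library left out. Without a filter 89 of 1444 piRNAs were lower, since more were tested.

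Bins called in ΔPAZ against wild type numbered 50 with 13 libraries, 63 with replicates 1 to 3, 44 with TMM, 23 without the 3 bins with most reads, 184 with DESeq2 on genome-mapped reads, 37 with replicate block, 1 with only the 2 groups, and 4 to 364 with 1 library left out. Only the 2 groups gave 342 bins for RNase against null. Bins shared by null and ΔPAZ numbered 17 with TMM, 7 without the 3 bins, 74 with DESeq2 and 18 with the block, and 1 to 150 with 1 library left out. Bins shared by RNase and ΔPAZ numbered 18, 8, 62 and 15, and 2 to 127. The cause was not tested.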

Other observations

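Chromosome V 17600001 to 17700000, with 28 protein-coding genes, went in opposite directions in the mutants: 115 ± 18.7 RPM in the null (SD, n = 5), 312 ± 78.6 in wild type (n = 5), 656 ± 272 in ΔPAZ (n = 3) and 2794 ± 105 in the RNase mutant (n = 3). Between the RNase mutant and the null its log2 fold change was 4.61 (SE 0.29; edgeR adjusted p = 1.5e-10). The bin was singled out after its values were seen.

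Antisense reads made up 24.3 ± 4.44% of all reads at piRNA loci in the null (SD, n = 5) and 5.57 ± 2.32% in wild type (n = 5). Null replicates 4 and 5 resembled each other (correlation of log2 RPM over bins 0.986) more than they resembled null replicates 1 to 3 (0.946 to 0.961), and genome bins are not independent replicates. Across genotypes, deviations from the genotype mean over bins had a mean correlation of 0.30 between replicates 4 and 5 of wild type and of the null, 0.12 between replicates 1 to 3 of both, and -0.20 across these sets. Of 100 ways to choose the libraries of the later set, 2 gave a difference as large (exact permutation p = 0.02, one-sided), a test chosen after the data were seen.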
